A study of Gossypium hirsutum with 18 samples.

How the data were processed

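Poly(A) RNA of upland cotton (Gossypium hirsutum, a tetraploid with A and D subgenomes) was sequenced from roots, stems and leaves of seedlings given water or 300 mM sodium sulfate for 12 h. There were 3 libraries in each of the 6 groups. Per the labels' protocols, total RNA was extracted with TRIzol, messenger RNA was isolated by its poly(A) tail, and libraries were made with a NEBNext Ultra RNA kit and read as pairs on a NovaSeq. Whether the kit marked strand is not stated, so reads of a gene and of an overlapping or antisense gene cannot be told apart. Nothing in the labels says that the 3 libraries of a group came from separate plants, so the p-values measure only the spread between these samples, which may be partly technical.

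The authors deposited 1 table that holds a count and an FPKM value for each of 70478 genes in each of the 18 libraries. Per the submitters' processing notes, HISAT, StringTie and edgeR were used, and no versions were given. The genome build was not given in the sources used here, so coordinates are printed as the deposited table gives them. The deposited counts are estimated counts that were rounded up to whole numbers: among 51622 low values the deposited count equalled the value implied by the FPKM, rounded up, in 99.998%, while 18.2% of the implied values lay within 0.1 of a whole number. The authors listed FPKM at 0.0001 wherever the count was 0, which was so for 307141 values. Names came from the descriptions in the table, which 58015 genes had and 12463 lacked. Cotton holds near-identical copies of many genes on its A and D chromosomes, and how reads were divided between such copies, or between members of a gene family, is uncertain.

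Total counts ran from 38868442 to 62568221 a library. The test fixed before the data were examined was limma on log2(FPKM + 1), because only FPKM values were expected. The table also held counts, so the test used here was edgeR's quasi-likelihood test on the deposited estimated counts, with TMM factors (0.768 to 1.28) and Benjamini-Hochberg adjustment over the genes tested. The limma test is given as an alternative. All 18 libraries entered 1 model with 6 groups, and the contrasts were sodium sulfate against water in each tissue and the differences of these changes between tissues. A gene was tested when its FPKM was at least 1 in at least 3 libraries (50798 genes), and called when its adjusted p was under 0.05 and its change at least 1 on the log2 scale. Changes are treated over control, with a standard error (SE). The SE was not estimated directly: it is the size of the change divided by the square root of the test's F statistic. It is approximate, above all for genes with few counts in a group. Means in CPM, computed by edgeR from TMM-scaled library sizes, are given with the SD over n = 3 libraries.

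Where all 3 libraries of a group had no count, a fold is a lower bound set against 3 counts over the group. Where a group had 1 to 3 counts, the ratio is given with an interval at 95% confidence. Bounds and intervals cover counting error only. Sequences without molecular identifiers are not independent molecules.

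Gene lists, the rule for the named genes, the filter, the thresholds and most alternatives were fixed before the data were examined. Per tissue the rule named the 5 highest and 5 lowest called genes with an informative description, a mean FPKM of at least 5 in the higher group and groups that did not overlap (chance alone separates 3 libraries from 3 in 10% of genes). It also named the most changed called member of each reactive oxygen and sulfur list, and of the 8 other lists with the highest share of members called. For each difference between tissues it named the 2 highest and 2 lowest genes. Further lists, written after the descriptions were seen, are called added lists where they appear. Lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, two-sided, adjusted over lists within a tissue. With an estimated correlation no list of any single tissue passed, and those p-values are printed beside the lists. Terms of 10 to 500 genes were tested with a one-sided Fisher's exact test against the 47183 tested genes with a GO term or the 26197 with a KEGG pathway. This test takes genes as independent, which genes that move together and A and D copies are not. Its p-values for terms therefore do not measure the spread between libraries and are far too small as evidence from 3 libraries a group.

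The scripts were tested on simulated counts for the real genes and libraries. The edgeR test recovered 49 of 100 genes changed 3-fold in the root comparison, 57 in the stem comparison and 61 in the leaf comparison, and 84, 82 and 86 of 100 genes changed 6-fold. False calls were 6, 3 and 6 of 50455 unchanged genes. These simulated changes were few, as many up as down, and placed only in genes above a floor of expression in controls. The simulation therefore cannot show errors of scaling where many genes change. Nor can it show false calls at the looser cutoff that many called genes bring. Alternatives were other pseudocounts, filters, scalings and models, and leaving out each of the 18 libraries. The use of edgeR in place of limma was decided after seeing the data, and library totals without TMM, a robust edgeR prior and DESeq2 were added then. Technical explanations were tested for 4 patterns, and the pattern of the treated stem libraries was added after the tests of the other patterns had been run. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and matplotlib 3.10.9.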

Results

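The series asks how seedlings of upland cotton respond to sodium sulfate, a salt that brings both sodium and sulfate to the plant, and it follows roots, stems and leaves in parallel. Poly(A) RNA was measured 12 h after 300 mM sodium sulfate or water, with n = 3 libraries for each tissue and treatment. Total counts per library were 43527067 to 62568221 in control roots, 38868442 to 47790032 in control stems, 49503404 to 53623616 in control leaves, 46232546 to 56007421 in treated roots, 46158851 to 62052172 in treated stems and 51331567 to 53751499 in treated leaves. Between 51247 and 57461 genes had a count in a library.

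Replicate libraries had Spearman correlations across genes of 0.903 to 0.949 in treated leaves, 0.915 to 0.96 in treated roots, 0.918 to 0.954 in treated stems and at least 0.957 in each control group. Of the treated leaf libraries, library 3 was most like the leaf controls, with a mean correlation of 0.894 against 0.830 and 0.808 for libraries 1 and 2. Without library 3, 11571 genes were called in leaves, against 9698 with it. Treated roots and treated leaves stayed closest to the controls of their own tissue, with median correlations of 0.797 and 0.832. Treated stems did not: their median correlation was 0.669 with the stem controls, against 0.763 with treated leaves, 0.731 with treated roots and 0.70 with control roots. Of 235 genes abundant in control roots (at least 50 CPM, at least 20 times the level of control stems) and not called lower in treated roots, 173 rose and 4 fell in treated stems. All were scarce in control stems, so few could have fallen. Their treated stem level had a median of 14.9% of the control root level, with quartiles of 2.83% and 45.3%. These values stand beside every stem result given here, and the tissue named for a library is that of its label.

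**Figure D1:**
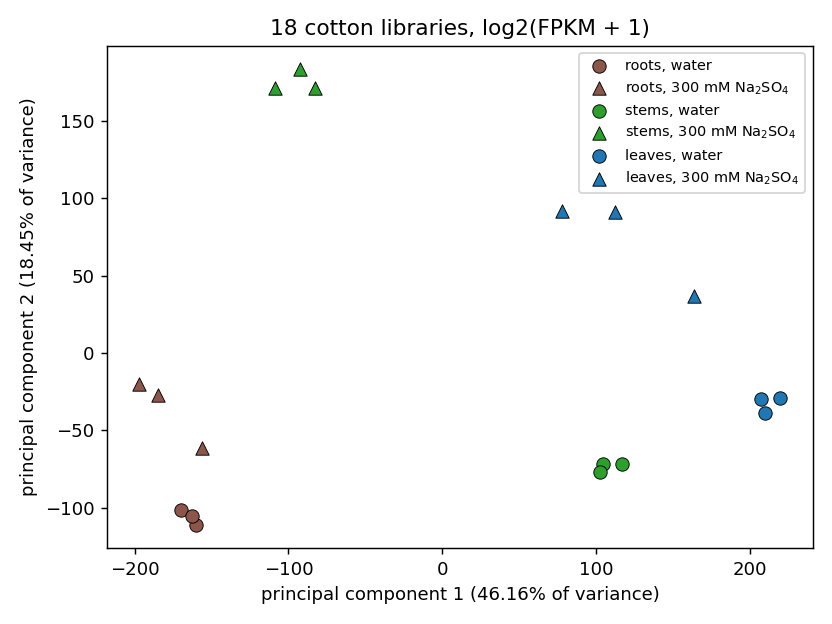
Each point is 1 of the 18 libraries, placed by the first principal component of log2(FPKM + 1) on the horizontal axis (46.16% of the variance) and the next on the vertical axis (18.45%), with circles for water, triangles for sodium sulfate and a color for each tissue. Treated stems lie apart from stem controls along both axes, on the side of the roots along the horizontal axis.

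In roots, most raffinose family enzymes were called higher. So were many heat shock proteins and histones. An HSP20-like chaperone (Gh_D05G1321, chromosome D05, 11632924 to 11633469) had no count in control roots and 81.8 ± 12.8 CPM (SD, n = 3) after sodium sulfate, at least 4530-fold higher. A phosphofructokinase 2 gene (Gh_D05G1688) was at least 2440-fold higher and a gene for JAZ8, a repressor of jasmonate signaling (Gh_A10G0388, chromosome A10, 3776510 to 3777261), at least 2140-fold higher. Among the genes that fell, osmotin 34 (Gh_D12G2246), a defense protein, went from 208.3 ± 48.9 to 0.218 ± 0.268 CPM, a log2 change of -9.96 ± 1.05 (SE, adjusted p = 1.26e-05), and pathogenesis-related 4 (Gh_D11G2595) had a log2 change of -7.92 ± 1.59. In all, 9412 genes were higher and 3602 lower of 50798 tested (25.6%). Limma on quantile-normalized log2(FPKM + 1), a change of both test and scaling that shifted the median of all genes in roots by -0.209, gave 6278 and 5018 (7814 and 3604 with limma without quantile normalization). Dropping the minimum change of 1 gave 6972 lower genes.

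Heat shock proteins had 57 of 110 members higher and 10 lower in roots (58 and 10 adjusted over the list alone, camera adjusted p = 7.26e-22), with adjusted p = 0.0802 with an estimated correlation. A mitochondrial small heat shock protein (Gh_A08G1538) was at least 1710-fold higher. Raffinose family enzymes, which make osmoprotective sugars, had 20 of 23 higher and none lower by edgeR (20 and 0 adjusted over the list alone, adjusted p = 2.73e-08), with adjusted p = 0.302 with an estimated correlation. The galactinol synthase 2 gene Gh_A09G2130 was at least 605-fold higher, a call lost under DESeq2 (adjusted p = 0.0549; adjusted p over its alternatives 1.5e-07 to 0.0549). LEA proteins and dehydrins had 18 of 34 higher and 1 lower (18 and 1 adjusted over the list alone, adjusted p = 0.005), with adjusted p = 0.442 with an estimated correlation.

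NADPH oxidases, which produce superoxide at the plasma membrane, had 13 of 17 members higher in roots (13 adjusted over the list alone, adjusted p = 9.97e-05), with adjusted p = 0.0802 with an estimated correlation. RBOHD (Gh_D05G1864) rose from 4.88 ± 1.66 to 93.0 ± 30.9 CPM. Alternative oxidases of the mitochondria had 4 of 8 higher (6 adjusted over the list alone, adjusted p = 2.08e-04), with adjusted p = 0.282 with an estimated correlation, and AOX2 (Gh_Sca047319G01) had a log2 change of 6.22 ± 0.481. Glutathione transferases had 36 of 107 higher and 11 lower (39 and 11 adjusted over the list alone, adjusted p = 0.0277), with adjusted p = 0.497 with an estimated correlation. The tau-class member Gh_A13G1313 had 3 counts in control roots and 5211 after treatment, a ratio of 1900 (648 to 9200). Class III peroxidases, enzymes of the cell wall, went the other way, with 13 of 118 higher and 30 lower (14 and 30 adjusted over the list alone, adjusted p = 8.4e-04), and adjusted p = 0.277 with an estimated correlation. Catalase 2 (Gh_D03G0021) fell by 2.94 on the log2 scale (SE 0.495).

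Among hormone genes in roots, the jasmonate list had 46 of 91 members higher and 12 lower (47 and 13 adjusted over the list alone, adjusted p = 9.1e-06), with adjusted p = 0.159 with an estimated correlation. In the added lists, clade A protein phosphatases 2C, negative regulators of abscisic acid signaling, had 19 of 24 higher (adjusted p = 6.58e-10; adjusted p = 0.236 with an estimated correlation), and NCED enzymes of abscisic acid synthesis had 9 of 14 higher (adjusted p = 2.18e-04; adjusted p = 0.217 with an estimated correlation). HAI2 (Gh_D12G2424) rose from 0.068 ± 0.118 to 168.5 ± 43.5 CPM and NCED3 (Gh_A01G0280) had a log2 change of 8.27 ± 1.38. NAC factors had 62 of 143 higher and 7 lower (68 and 9 adjusted over the list alone, adjusted p = 1.11e-05), with adjusted p = 0.258 with an estimated correlation.

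For sulfur, the high-affinity type sulfate transporter gene Gh_D13G0546 (sulfate transporter 1;3), with no count in stems or leaves, fell from 22.0 ± 11.1 to 1.495 ± 0.803 CPM in roots, while 9 of 22 sulfate transporters were higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.0518, which did not pass). The serine acetyltransferase gene Gh_D13G1404, whose product makes a precursor of cysteine, rose by 5.50 ± 0.63 on the log2 scale. Sulfate assimilation genes as a list had 6 of 29 higher and 3 lower (6 and 3 adjusted over the list alone, adjusted p = 0.908). Added lists also put 66 of 134 histone genes higher and 4 lower (adjusted p = 8.59e-09; adjusted p = 0.064 with an estimated correlation) and 33 of 94 aquaporins higher and 6 lower (adjusted p = 0.00625; adjusted p = 0.509 with an estimated correlation). GO terms enriched among genes higher in roots included response to chitin (194 of 376 genes, 2.82-fold, adjusted p = 4.16e-45) and response to high light intensity (87 of 135, 3.52-fold, adjusted p = 2.83e-29). Terms enriched among lower genes included the endoplasmic reticulum lumen (19 of 47, 5.70-fold, adjusted p = 1.64e-07) and ATP citrate synthase activity (7 of 11, 8.97-fold, adjusted p = 3.18e-04).

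**Figure D2:**
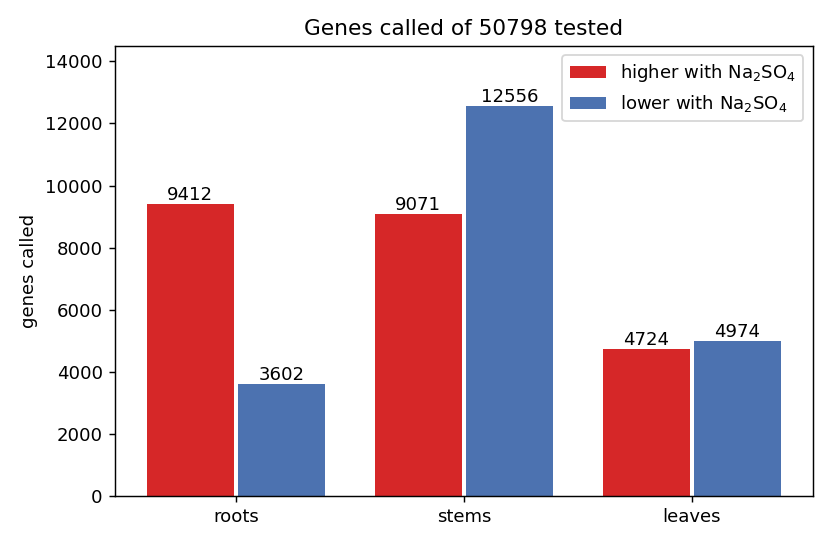
Bars give the number of genes called higher (red) and lower (blue) with sodium sulfate in each tissue, from 0, of 50798 tested. Roots had 9412 higher and 3602 lower, stems 9071 and 12556, and leaves 4724 and 4974, and the split moved to 6099 and 18478 in stems and to 6611 and 3971 in leaves when libraries were scaled by their totals (3750 and 5836 in leaves with median-ratio scaling).

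In stems, most nuclear light-harvesting genes, flavonoid enzymes and histones were called lower. All tested alternative oxidases and many genes of sulfur assimilation and glutathione transferases were called higher. The sulfate transporter 3;1 gene Gh_A11G1147 (chromosome A11, 13619978 to 13624291) rose from 3.64 ± 0.936 to 1384 ± 265 CPM, a log2 change of 8.57 ± 0.559 (adjusted p = 2.27e-07). The serine acetyltransferase gene Gh_A13G1132 rose from 2.72 ± 0.996 to 500.7 ± 125 CPM, and the alternative oxidase 1A gene Gh_A12G2493 from 0.513 ± 0.0543 to 662 ± 430 CPM. Genes with no count in treated stems included a zinc transporter 1 precursor (Gh_Sca005105G01), at least 2170-fold lower, and formin homology 1 (Gh_D02G0085), at least 1120-fold lower. In all, 9071 genes were higher and 12556 lower (42.6% of those tested). The split was 5233 and 15695 with limma on log2(FPKM + 1) and 6099 and 18478 with library totals, which shifted the median of all genes in stems by -0.355 and -0.552. Median-ratio scaling shifted it by 0.117, and limma with quantile normalization by 0.125.

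Sulfate assimilation and cysteine synthesis had 16 of 29 members higher and 3 lower in stems (17 and 3 adjusted over the list alone, adjusted p = 2.89e-05), with adjusted p = 0.315 with an estimated correlation. Glutamate-cysteine ligase (Gh_D09G1826), the entry enzyme of glutathione synthesis, had a log2 change of 2.58 ± 0.35. In roots the same gene was called lower, with log2 changes of -1.29 to -0.739 over 32 alternatives, of which 6 lost the call. The KEGG pathway sulfur metabolism was enriched among higher genes (45 of 129, 1.85-fold, adjusted p = 2.7e-04). Glutathione transferases had 52 of 107 higher and 15 lower (52 and 15 adjusted over the list alone, adjusted p = 1.33e-04), with adjusted p = 0.338 with an estimated correlation, and the tau-class gene Gh_A13G1329 went from 4 to 51561 counts. All 8 tested alternative oxidases were higher (8 adjusted over the list alone, adjusted p = 1.03e-04), with adjusted p = 0.315 with an estimated correlation. NADPH oxidases had 11 of 17 higher and 2 lower (11 and 2 adjusted over the list alone, adjusted p = 0.0014), with adjusted p = 0.315 with an estimated correlation. Ascorbate peroxidases had 15 of 22 lower and none higher by edgeR (15 and 0 adjusted over the list alone, adjusted p = 0.00183), and adjusted p = 0.315 with an estimated correlation.

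Of 125 nuclear genes for light-harvesting and photosystem subunits (an added list), 112 were lower and 1 higher in stems (adjusted p = 8.72e-21; adjusted p = 0.344 with an estimated correlation). Their mean log2(FPKM + 1) went from 6.42 ± 0.30 to 3.18 ± 0.22. Chloroplast thylakoid was the term with 227 of 323 genes among those lower (2.79-fold, adjusted p = 1.27e-61 by Fisher's exact test, which takes genes as independent). Copies of plastid-type genes, a list written after the results were seen, moved the other way, with 79 of 85 higher by edgeR. The KEGG pathway photosynthesis was also enriched among higher genes (75 of 240, 1.66-fold, adjusted p = 9.73e-05). Flavonoid enzymes had 14 of 17 lower and 1 higher (14 and 1 adjusted over the list alone, adjusted p = 2.59e-04), with adjusted p = 0.38 with an estimated correlation, and dihydroflavonol 4-reductase (Gh_A06G0066) went from 354.7 ± 33.7 to 4.63 ± 2.5 CPM. Histones had 72 of 134 lower and 5 higher (adjusted p = 4.06e-06; adjusted p = 0.344 with an estimated correlation). Expansins and xyloglucan endotransglucosylases, which loosen cell walls, had 54 of 106 lower and 20 higher (55 and 20 adjusted over the list alone, adjusted p = 0.0621, which did not pass).

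Proline synthesis had 5 of 7 members higher in stems (5 adjusted over the list alone, adjusted p = 0.0138), with adjusted p = 0.315 with an estimated correlation, and P5CS1 (Gh_D04G1204), the rate-limiting enzyme, rose by 6.57 ± 0.663 on the log2 scale. WRKY factors had 97 of 216 higher and 28 lower (97 and 28 adjusted over the list alone, adjusted p = 1.76e-05), with adjusted p = 0.315 with an estimated correlation. Protein phosphatases 2C had 53 of 176 higher and 25 lower (53 and 25 adjusted over the list alone, adjusted p = 0.0199; adjusted p = 0.38 with an estimated correlation), a direction that flipped with limma on log2(FPKM + 1), at 29 and 45, and with library totals, at 36 and 50. Sulfate transporters as a list had 8 higher and 7 lower, and 7 and 9 with limma (8 and 7 adjusted over the list alone, adjusted p = 0.224). The named expansin-like B1 gene Gh_A03G0046 and the transporter Gh_D03G0082 had no count in control stems and 17.5 ± 29.7 and 56.3 ± 95.7 CPM in treated stems, nearly all of it in 1 library for each gene. They lost their calls with limma on log2(FPKM + 1) but not with its smaller pseudocounts or with quantile normalization. The expansin lost its call also with each tissue fitted alone (adjusted p up to 0.0671 and 0.0594 over the alternatives of the 2 genes).

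**Figure D3:**
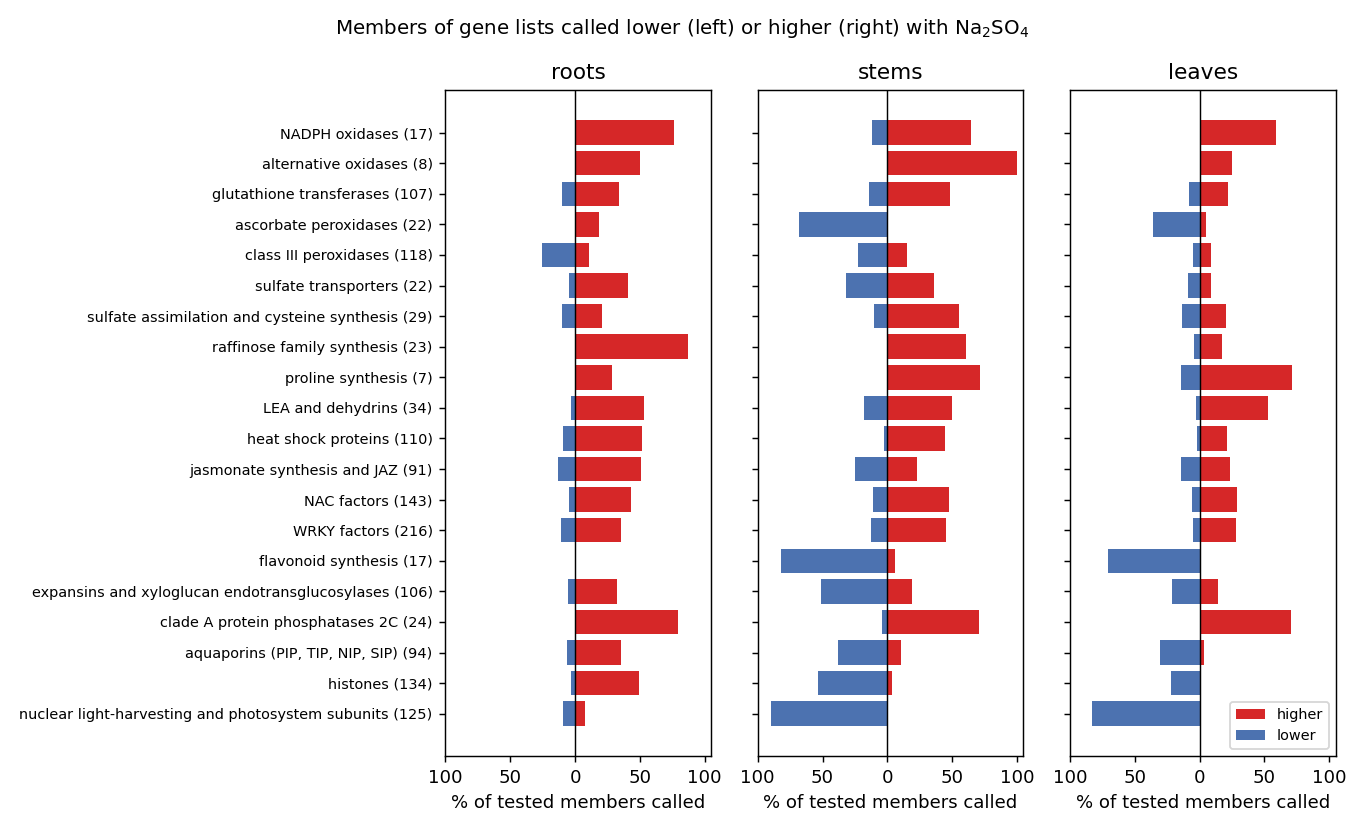
Bars to the right give the percent of a list's tested members (their number in parentheses) called higher and bars to the left the percent called lower, in roots, stems and leaves. All 8 alternative oxidases were higher in stems, 20 of 23 raffinose family genes in roots, and 112 and 104 of 125 nuclear light-harvesting and photosystem genes were lower in stems and leaves. In stems, the balance of sulfate transporters (8 higher, 7 lower) flipped with library totals (7 and 8), and that of jasmonate genes (21 and 23) with median-ratio scaling (22 and 21). In leaves, that of class III peroxidases (10 and 6) flipped with DESeq2 (12 and 18) and that of sulfate assimilation genes (6 and 4) with DESeq2 (6 and 7). In roots, nuclear light-harvesting genes (10 and 12) flipped with median-ratio scaling (11 and 10).

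In leaves, most photosynthesis genes and flavonoid enzymes and some aquaporins were called lower. Most clade A protein phosphatases 2C and LEA proteins were called higher. P5CS2 (Gh_A01G1899, chromosome A01, 98932667 to 98937902) rose from 0.288 ± 0.499 to 163.9 ± 71.8 CPM, a log2 change of 9.15 ± 1.33 (adjusted p = 3.44e-04). Senescence-associated gene 29 (Gh_D01G0202) was at least 1140-fold higher and an isocitrate lyase gene (Gh_A03G0958) at least 578-fold higher. Expansin A5 (Gh_A10G1374) was at least 194-fold lower and a GDSL-like lipase gene (Gh_A01G0653) at least 425-fold lower. In all, 4724 genes were higher and 4974 lower (19.1% of those tested), and 6611 and 3971 with library totals, which shifted the median in leaves by 0.207. The split leaned the other way with median-ratio scaling, at 3750 and 5836 (a shift of -0.125), and with DESeq2, at 4420 and 6952. Without control leaf library 3 the count of higher genes was 2875, and without treated leaf library 2 it was 3064. Leaving out a stem or root library, which holds no leaf values, mostly moved the leaf split as well. It was 3668 and 5369 without control stem library 1 (a shift of -0.113) and 3738 and 5494 without control root library 3 (-0.0949). The split stayed near even without control root library 2 (4657 and 4964) or treated root library 3 (4544 and 4831). Without treated leaf library 1 the count of lower genes was 3085. It was 7241 higher genes with no minimum change and 3146 with an FPKM of at least 5.

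Nuclear light-harvesting and photosystem genes (an added list) had 104 of 125 lower and none higher by edgeR in leaves (adjusted p = 8.5e-31; adjusted p = 0.224 with an estimated correlation). Their mean log2(FPKM + 1) was 8.78 ± 0.0605 in control leaves and 6.83 ± 0.957 in treated leaves, where the libraries were at 6.86, 5.86 and 7.78. The wider photosynthesis list had 128 of 218 lower and none higher by edgeR (140 and 2 adjusted over the list alone, adjusted p = 2.05e-24), with adjusted p = 0.335 with an estimated correlation. Flavonoid enzymes had 12 of 17 lower (12 adjusted over the list alone, adjusted p = 2.92e-05), with adjusted p = 0.335 with an estimated correlation. Leucoanthocyanidin dioxygenase (Gh_A08G1593) went from 773 ± 279 to 59.0 ± 55 CPM, a call lost without treated leaf library 1 (adjusted p = 0.0513; range over its alternatives 5.84e-05 to 0.0513). Aquaporins had 29 of 94 lower and 3 higher (added list, adjusted p = 1.05e-05; adjusted p = 0.375 with an estimated correlation).

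Clade A protein phosphatases 2C had 17 of 24 members higher in leaves (added list, adjusted p = 6.4e-08; adjusted p = 0.375 with an estimated correlation), and HAI1 (Gh_A05G3590) had log2 changes of 9.35, 7.62 and 6.70 in roots, stems and leaves. The factors that bind abscisic acid response elements had 7 of 18 higher (added list, adjusted p = 9.81e-04; adjusted p = 0.375 with an estimated correlation), among them ABF2 (Gh_D05G2495), at 3.14 ± 0.713. LEA proteins and dehydrins had 18 of 34 higher and 1 lower (19 and 2 adjusted over the list alone, adjusted p = 0.00285), with adjusted p = 0.43 with an estimated correlation. NADPH oxidases had 10 of 17 higher (10 and 1 lower adjusted over the list alone, adjusted p = 0.00559), with adjusted p = 0.335 with an estimated correlation, and RBOHB (Gh_D11G2743) went from 3 to 3051 counts, a ratio of 855 (292 to 4150). Ascorbate peroxidases had 8 of 22 lower and 1 higher (10 and 1 adjusted over the list alone, adjusted p = 0.00559), with adjusted p = 0.335 with an estimated correlation. APS reductase 3 (Gh_D06G1636), which reduces activated sulfate, fell by 4.46 ± 0.26 on the log2 scale in leaves (adjusted p = 1.72e-06), and in stems its log2 change was -4.18.

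Some named genes passed in the test used but not in several alternatives. An Fe superoxide dismutase 2 gene (Gh_D07G0457) had a log2 change of 2.11 in roots (adjusted p = 0.0365; 0.00701 to 0.193 over its alternatives) and -2.15 in leaves (adjusted p = 0.0389; 0.00374 to 0.229). An ascorbate peroxidase 3 gene (Gh_D03G0074) had 2.81 in roots (adjusted p = 0.0469; 0.00144 to 0.157), and nicotianamine synthase 3 (Gh_D13G1890) had 6.06 (adjusted p = 0.0294) and 0.68 without treated root library 3 (adjusted p = 0.77; 0.0147 to 0.77 over its alternatives).

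**Figure D4:**
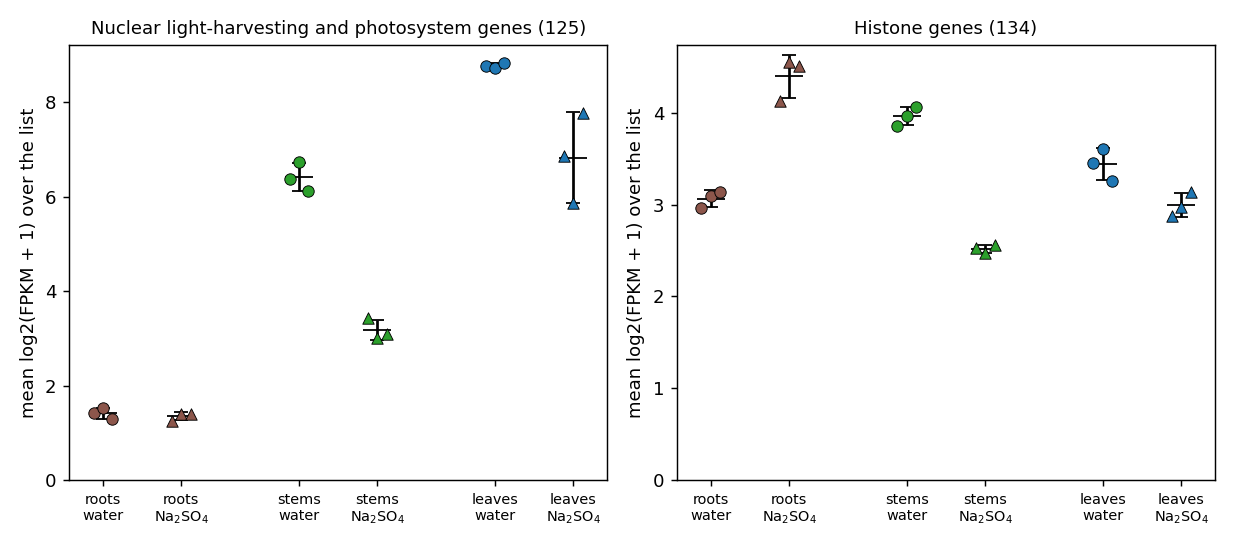
Points are libraries, and the bar and whiskers are the mean and SD of n = 3, of the mean log2(FPKM + 1) over 125 nuclear light-harvesting and photosystem genes (left) and 134 histone genes (right), for water (circles) and sodium sulfate (triangles). Light-harvesting genes went from 6.42 to 3.18 in stems and from 8.78 to 6.83 in leaves. Histones went from 3.06 to 4.40 in roots, from 3.96 to 2.52 in stems and from 3.437 to 2.995 in leaves.

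The responses of the tissues were compared gene by gene. Histones rose in roots relative to stems, with 85 of 134 differing that way and 3 the other (adjusted p = 1.26e-13; adjusted p = 0.0361 with an estimated correlation), and relative to leaves, with 76 and 3 (adjusted p = 8.34e-16; adjusted p = 0.00845 with an estimated correlation). Aquaporins had 42 of 94 higher in the root response than in the leaf response and 5 lower (adjusted p = 2.56e-07; adjusted p = 0.372 with an estimated correlation). Sulfate assimilation genes had 12 of 29 higher in the stem response than in the leaf response and none lower by edgeR (13 higher adjusted over the list alone, adjusted p = 4.55e-07), with adjusted p = 0.548 with an estimated correlation. Raffinose family genes had 15 of 23 higher in the root response than in the leaf response (17 adjusted over the list alone, adjusted p = 6.51e-05), with adjusted p = 0.513 with an estimated correlation. The difference of the response passed for 20816 genes between roots and stems (13022 higher in roots, 7794 lower), 14287 between roots and leaves (8818 and 5469) and 9448 between stems and leaves (3774 and 5674).

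These splits moved with the scaling and with the test. The limma and DESeq2 values change both at once. Between roots and stems they were 17489 and 4475 with library totals, 17737 and 5239 with limma on log2(FPKM + 1), and 10088 and 10167 with limma and quantile normalization. Between roots and leaves they were 7779 and 7698 with library totals and 8220 and 7769 with limma and quantile normalization. Without treated root library 2 the lower count was 3512, and without treated leaf library 2 it was 3542. Between stems and leaves they were 2194 and 16541 with library totals, 2967 and 15374 with limma, 5253 and 5363 with limma and quantile normalization, 5100 and 3925 with median-ratio scaling and 6303 and 5211 with DESeq2. The 5674 genes lower in the stem than in the leaf response were 3283, 3306 and 3247 without control stem library 1, 2 or 3, 3250, 3569 and 3054 without control leaf library 1, 2 or 3, 3679 and 3589 without treated stem library 2 or 3, and 3000 without treated leaf library 3. Leaving out a root library, which holds no stem or leaf values, could move the split as well. Without control root library 1 it was 4719 higher and 3790 lower, with the median shifted by 0.235. Leaving out 1 library turned the balance to more higher than lower genes, except without control root library 2, treated root library 3 or treated leaf library 1.

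Stems and leaves shared 3174 genes called higher and 3672 called lower, where independent lists of these sizes would share 843.56 and 1229.4, and 135 were higher in stems and lower in leaves. Across genes, which are not independent replicates, the log2 changes of stems and leaves had r = 0.545, against 0.079 for roots and stems and 0.042 for roots and leaves. Roots and stems shared 3004 genes called higher (1680.7 if independent) and 986 called lower (890.32), and 2808 were higher in roots and lower in stems (2326.4). In all 3 tissues 1304 genes were higher and 357 lower, where independent lists would share 156.3 and 87.2.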

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

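In this part the tests of depth behind the genes without counts and of an exchange of stem samples were chosen after the result was seen, as was the pattern of the treated stem libraries itself.

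Each difference between tissues given here is flagged by its own test of the difference, and fitted values of single genes rest on groups with no counts, so they are no bounds. Between roots and stems 20816 genes differed, as did 20 of 54 gene lists and 42 of the 65 genes named for either tissue. With an estimated correlation 1 gene list, the histones, differed there, and likewise 1 between roots and leaves and 0 between stems and leaves. Expansin B2 (Gh_A08G1231) had a fitted difference of 23.59, with 0 counts in control roots and 1005 in treated roots but 1951 in control stems and 0 in treated stems, and expansin B3 (Gh_D12G1393) had 21.15. A cupredoxin (Gh_A13G0336) had -17.06 and a berberine family gene (Gh_D02G0213) -16.76. Between roots and leaves 14287 genes, 17 gene lists and 43 of 63 named genes differed. A pectin lyase-like gene (Gh_D07G0091) had 18.94, a JAZ8 gene (Gh_A09G0741) 18.85, senescence-associated gene 29 (Gh_D01G0202) -14.09 and an oxygenase (Gh_A13G2341) -13.71. The call of Gh_A09G0741 was lost without control leaf library 2 and that of Gh_D01G0202 without control root library 3 (adjusted p = 1 in both, by edgeR). Between stems and leaves 9448 genes, 11 gene lists and 26 of 61 named genes differed. A plastid-type psbB gene (Gh_A02G0990) had 18.64, a transporter (Gh_D03G0082) 15.61, lost with limma and without control leaf library 2 (adjusted p up to 0.201 over its alternatives), a HCO3- transporter family gene (Gh_A09G2136) -13.51 and a glyoxalase family gene (Gh_A03G1909) -13.17.

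Treated stem libraries were less like the stem controls (median Spearman 0.669) than like treated leaves (0.763) or control roots (0.70). All 6 treated root and leaf libraries were closer to their own controls than to stem controls, by a difference of at most -0.0503. This speaks against an exchange with treated stems only if treated stems stay closest to stem controls. The libraries labelled as treated stems did not, so an exchange is not decided. Root tissue in the treated stem samples cannot be told apart from a response of stems. Of the 235 root-abundant genes, 73.62% rose in stems, between the 80% that root tissue was set to need and the 50% set against it. They were picked as scarce in control stems, so few could fall, and 9071 of all 50798 tested genes were called higher there. Of the 235, 54 rose in leaves (49 in stems and leaves both), and 33 stayed under 1% of the treated root level. Root hair and nitrate uptake genes (16, an added list) had a mean log2(FPKM + 1) of 2.86 in control roots. In stems it went from 0.735 ± 0.116 to 1.06 ± 0.222. The preset root markers went from 1.80 to 1.35 in stems, but stood at 0.509 in control roots, so they cannot mark root tissue. Across the 235 genes the treated stem level had quartiles of 4.81% and 67.9% of the treated root level. That spread argues against 1 even share of root tissue like the treated roots as the only source of these levels. Some root tissue beside a response of stems stays open. A single wrong label, or other parts of the stem being sampled, was not tested. Every stem count may carry any of these. The bounds were set before the 73.62% was computed, but after the Spearman values and the levels of root marker genes had been seen.

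Called genes without a count in 1 group of a tissue numbered 696 switched on and 72 off in roots, 588 and 832 in stems, and 258 and 258 in leaves. A copy with the same description on the homoeologous chromosome could be compared for 141 of these calls in roots, 219 in stems and 79 in leaves. Where both copies of a pair were such calls, the pair entered from each side. Pairs could also recur between tissues, and distinct pairs were not counted. In these 439 comparisons 63.33% of copies were called the same way. Their median log2 change toward the gene was 4.65 over all 439 (quartiles 2.14 and 7.62). Reads moved between copies are argued against there as the only source, since a move alone would shift the copy the other way. Only 1.14% were called the opposite way, which says little, since few counts would not shift a well-expressed copy. Calls without such a copy were not tested. Depth is argued against by a highest ratio of 1.242 between total counts of the groups compared. A response to sodium sulfate may account for these genes and stays a hypothesis, as does a change of the tissue sampled in stems.

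Of 134 histone genes 66 rose in roots and 72 fell in stems, and 37 of 59 mitotic cyclin and kinesin genes rose in roots while 33 fell in stems. In leaves 1 histone gene rose and 30 fell (23 fell with library totals and 46 with DESeq2). Scaling is argued against for roots and stems, since 3 other scalings kept at least 91.67% of the number of histone calls in both of these tissues. A larger share of root tips in treated root samples cannot be told apart from more cell division, because only 5 root apex factors were tested, with a median log2 change of 0.7006 (quartiles 0.61 and 1.51) and none called by edgeR. Root hair and nitrate uptake genes (16, an added list) fell in roots, from a mean log2(FPKM + 1) of 2.86 ± 0.198 to 2.02 ± 0.19. Either reading allows such a fall. The biological reading was not tested apart from these.

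Other splits of the same libraries were counted for each result. With 10 splits of 3 against 3 no share under 0.05 is possible, and the real counts were 13014, 21627 and 9698 in roots, stems and leaves (1 split of 10 each) against highest others of 3, 1 and 3. For the differences, regrouping the libraries of a tissue removes its response as well as the difference, so no rank is read as excluding chance. Between roots and leaves the real split ranked first (1 of 24 splits), with 14287 genes. The highest other, 8490, kept the real grouping of roots. Between roots and stems the real split also ranked first (1 of 24), with 20816 genes. The highest other, 20776, kept the grouping of both tissues but exchanged control and treated in 1 of them. That split tests the sum of the responses of roots and stems, not their difference. Chance is not excluded between stems and leaves, where 6 of 24 splits gave at least 9448 genes, the highest of the others 19958. Splits with such large counts keep or mirror the real grouping of 1 of the tissues, and the split with 20776 that of both, a structure of the samples: the 19, 18 and 18 splits that kept no real grouping gave at most 4, 3 and 1 genes.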

How the results depend on the processing

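The edgeR test of counts was put in place of limma on log2(FPKM + 1), the test fixed beforehand, after seeing the data, and library totals, a robust edgeR prior and DESeq2 were added then. No named gene changed sign in an alternative, while the balance of higher and lower genes and of some gene lists flipped with the scaling or with the test, as given beside those counts. Between stems and leaves the balance of genes flipped also when 1 library was left out, with the exceptions given there. Leaving out 1 library gave 10176 to 13535 genes in roots (higher 7257 to 9680, lower 2919 to 3938), 19773 to 21728 in stems (8767 to 10082, 10590 to 12544) and 6859 to 11571 in leaves (2875 to 4657, 3085 to 7087). The differences ranged over 18562 to 21608 between roots and stems (11057 to 12962, 7448 to 9332), 11599 to 15854 between roots and leaves (7506 to 10460, 3512 to 5394) and 7084 to 9958 between stems and leaves (3237 to 5265, 3000 to 5583). Some counts from all 18 libraries lay above these ranges. They were 12556 lower in stems, 4724 higher in leaves and 13022 higher between roots and stems. So were 5469 lower between roots and leaves and 5674 lower between stems and leaves.

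Counts that moved by over 1.5 times are given with the setting, and the cause was not tested unless the setting itself changes the genes tested. No minimum change gave 6972 lower in roots and 7241 higher in leaves. An FPKM of at least 5, which tests fewer genes, gave 3146 higher in leaves, 3324 lower between roots and leaves and 3543 lower between stems and leaves. Limma gave 5233 higher in stems with a pseudocount of 1, and likewise without trend (5233) and robust (5233), 6014 with a pseudocount of 0.1 (19492 lower) and 5711 with 0.5. With 0.1 it gave 5171 lower between roots and stems, and with 0.1 and 0.5 it gave 8514 and 8488 lower between roots and leaves. Between stems and leaves it gave 18341 genes (15374 lower) with 1, 20477 (17794) with 0.1, 20302 (17285) with 0.5, 18327 (15366) without trend and 18310 (15352) robust. Library totals gave 4475 lower between roots and stems and 18735 between stems and leaves (2194 higher, 16541 lower), and DESeq2 6303 higher there.

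Of the lists fixed beforehand, camera called 16 in roots, 13 in stems and 13 in leaves, an estimated correlation 0, 0 and 0, and fry, which tests a list's own direction, 26, 22 and 22. Of the added lists, 9, 9 and 9 were called, 0, 0 and 0 with an estimated correlation, and 14 in stems with fry. With the replicate number as a block, roots had 8260 higher and 3414 lower, stems 8300 and 12240, leaves 3983 and 4438, and the differences 12185 and 7153, 7627 and 4669, 2998 and 4394. Deviations of same-numbered control and treated libraries had correlations of -0.096 to 0.249, over 0.1 in 2 of 9 pairs, both of roots (0.113 and 0.249), where differently numbered pairs ran from -0.215 to 0.137. Pairing by number is not established, and in roots it is left open. Counts of 0 limit folds to the bounds given.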

Other observations

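The test of plastid-type genes removed from the counts and that of mitochondrial-type genes were fixed before their results were seen, and the comparison of subgenomes was made after the other results were seen.

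In stems, copies of plastid-type genes (psb, psa, atp and rpo genes among the gene models) moved against the nuclear genes of photosynthesis. Of 85 tested, 79 were higher in treated stems, with a median log2 change of 4.15, and their share of all counts went from 0.00953% to 0.156%. In roots 42 were higher, and in leaves none were higher and 4 lower by edgeR. Of 14 mitochondrial-type copies, 28.57% were higher in stems, between the bounds set beforehand. Their median log2 change was 0.326 (quartiles -0.514 and 1.68), against quartiles of 3.69 and 4.88 for the plastid-type copies. Their share of counts went from 0.00826% (SD 0.000683) to 0.00766% (SD 0.000661). For these 14 copies, this argues against a general carry-over of RNA without poly(A) tails as large as the plastid-type rise. A smaller one is left undecided. The 112 nuclear light-harvesting and photosystem genes called lower stayed lower (100%) once the 85 plastid-type genes were removed from the counts. Removing 0.156% of the counts could hardly have given another outcome, so this says no more than the small share itself.

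In roots, added lists showed 110 of 240 AP2/ERF factors higher and 17 lower (adjusted p = 2.59e-05; adjusted p = 0.14 with an estimated correlation). Heat stress factors, fixed beforehand, had 23 of 66 higher and none lower by edgeR (23 adjusted over the list alone, adjusted p = 2.46e-05), with adjusted p = 0.258 with an estimated correlation. Expansins and xyloglucan endotransglucosylases had 34 of 106 higher and 6 lower in roots (35 and 6 adjusted over the list alone, adjusted p = 0.0273), with adjusted p = 0.497 with an estimated correlation. Of tested genes on A and on D chromosomes, 25.8% and 25.8% were called in roots, 43.0% and 42.7% in stems and 19.3% and 19.3% in leaves, and the difference was not tested.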
